A study of Mus musculus with 3 samples.

How the data were processed

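The libraries hold the CD45+ leukocytes of sciatic nerves from NOD.AIRE GW/+ mice aged 15 weeks. This strain carries an altered copy of Aire, the gene whose product lets the thymus display tissue antigens, on the autoimmune-prone NOD background. The 3 libraries are of this 1 genotype, and wild-type nerves were not analysed here. Comparisons therefore run between cell types of the same nerves and measure no effect of genotype. Libraries 1 and 2 are 3′ libraries and library 3 is a 5′ library, per the labels. The cell numbers that the labels give for the 3 samples (6033, 2333 and 3274) equal those of the 3 groups of cells in the deposited count table, and this paired cells with samples. In the authors' cell table the name of library 1 alone ends in "pos", a term the labels do not explain.

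The deposited table gives the UMI count of 17168 genes in each of 11640 cells, as whole numbers with no scaling, and 38 of these genes have no count. Per the submitters' processing notes, Cell Ranger 5.0.1, Seurat 4.0 and the mouse build mm10 were used, without their roles. Each cell also has a total UMI count, a number of detected genes and a mitochondrial percent in the authors' cell table. The totals and gene numbers recomputed from the counts equal the deposited ones in all 11640 cells, and so does, to rounding, the percent of UMIs from 13 mitochondrial genes. Cells had been filtered by the authors, as the values show: the most genes in a cell is 2997 and the highest mitochondrial percent is 12.49. An upper limit on gene number takes away the deepest cells. The share of cells with 2500 genes or more is 44.4% of plasma cells, 42.2% of conventional dendritic cells, 21.1% of pDCs and 18.9% of macrophages, against 2.62% of B cells. The fewest UMIs in a cell is 491 and the fewest genes 258. Median UMIs per cell were 3011, 4156 and 3713 in libraries 1, 2 and 3, and median genes 1194, 1655 and 1611.5. All deposited cells were kept.

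Cell classes are the 10 names that the authors gave to 14 clusters: B, Cd4, Cd8, Treg, gdT/NK/NKT, Mixed, Mac, cDC, pDC and Plasma. Scrublet, run per library with default settings, called 84 of 11640 cells doublets (75, 8 and 1 in libraries 1, 2 and 3). The authors' class Mixed is their cluster 11, led by Il17a, Trdv4, Cd163l1 and Il17f, and it is written of here under the authors' name. UMIs were summed over the cells of each class in each library. Classes with at least 20 cells in every library were tested: 8 classes, without pDC (2 cells in library 2) and Plasma (7 cells in library 1). For macrophages against T cells the classes Cd4, Cd8 and Treg were added together, which leaves 6 classes.

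Sums were tested with edgeR's quasi-likelihood F-test after TMM scaling and filterByExpr, with the library as a block, so that each class is compared with the others of its own library. The pairing can be seen in the data: deviations of the same library from the class means correlate between macrophages and T cells at 0.671, 0.531 and 0.724 over 10613 genes, and between CD4 and CD8 T cells at 0.836, 0.789 and 0.915 over 10895 genes. Between macrophage clusters M1 and M3 they correlate at 0.651, 0.525 and 0.739 over 4891 genes. Replicates were given no order. The authors' classes were drawn from the same counts, so p-values between classes are no evidence that the classes are distinct. The tests were each class against the mean of the other 7 (read for the TNF axis), macrophages against T cells, CD4 against CD8 T cells, and macrophage cluster M1 against M3. A gene is called at an adjusted p (Benjamini-Hochberg over all tested genes) under 0.05. Standard errors of log2 fold changes are the fold change over the root of F. Levels are counts per 1000000 (CPM), scaled by TMM and given as mean ± SD over 3 libraries. Single libraries quoted for Aire, and in the closing section for pDCs and for Tnf of macrophages, are unscaled CPM. The common dispersions were 0.0204, 0.0240 and 0.0286 for the 8 classes, the 6 classes and the macrophage clusters.

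Macrophage clusters were rebuilt from the 581 macrophages. Values were log(1 + x) of counts scaled to 10000 per cell, for 1000 variable genes ranked within libraries, scaled within each library, which is how libraries were brought together. Mitochondrial, ribosomal, antigen-receptor segment and unnamed predicted genes were set aside, and a gene had to be seen in at least 10 cells. An exact singular value decomposition to 10 components, 20 shared neighbours and Leiden at resolution 0.5 gave 5 clusters. Only M1 and M3 have at least 20 cells in every library, so the planned test of each cluster against the others became M1 against M3. Clusters were drawn from the same counts as the test, so its p-values are no evidence that the clusters are distinct.

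Fixed lists of genes, 24 in all, were written before the data were examined: TNF ligands and receptors with proximal signalling, NF-kB targets, interferon-gamma response, type I interferon response, MHC class II presentation, T cell-attracting chemokines and monocyte-attracting chemokines. Macrophage lists were epineurial resident, endoneurial resident, lipid-handling, complement and monocyte-derived. T cell lists were Th1, Th17, cytotoxic, inhibitory receptor, regulatory T cell, tissue residency and naive. The others were glycolysis, proliferation, dissociation response, myelin, and hedgehog and neurotrophic genes. Lists with at least 3 tested members were tested with camera at an inter-gene correlation of 0.01, with p adjusted over the lists of a contrast. The alternatives were a correlation estimated per list and fry. Counts of called list members are given over all genes and adjusted over the list alone.

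The genes named in the text follow a rule that was also written before the data were examined. It takes all 18 genes of the TNF axis in every class, and in the 3 pairwise tests the 8 genes with the largest rises and the 8 with the largest falls. These had to be called, changed in the same direction in every library and reach a mean log2 CPM of 5, leaving out a fixed list of cell type markers. Some genes that lead clusters of the authors were not on that list and stayed in. To these it adds the 4 members with the smallest p of each list that passed camera. In the report, tests of 1 class against the rest serve the TNF axis alone. The closing section also quotes them for members of the fixed lists in classes that no pairwise test covers, and those genes were picked outside the rule, after the results were seen.

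For the share of cells with Tnf, cells were thinned at random to 1000 UMIs each, and the 725 cells with fewer were left out. Of these, 624 were of the class Cd4 (593 from its low-depth deposited cluster 5) and 10 were macrophages. The share in CD4 T cells thus describes the deeper cells of that class. Shares of cells carry 95% Clopper-Pearson intervals of counting error alone. A count of 0 is read as up to 3 counts. Where a group holds 1 to 3 UMIs, the ratio of summed UMIs is given with its counting interval. Gene coordinates are 1-based, from GENCODE M21 on mm10, and genes were paired with them by symbol.

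The tests were tried on negative-binomial counts with 200 genes changed, 100 by 2-fold and 100 by 4-fold. Depths and dispersions were the real ones, and the mean of each gene was its average over the classes of a library. Apart from the changed genes the simulated classes were thus alike, unlike the real ones, so the shares below need not hold in the real comparisons. At 2-fold, 55% were recovered for macrophages against T cells, 68% for CD4 against CD8, 64% for macrophages against the rest and 47% for M1 against M3. At 4-fold these shares were 88%, 91%, 87% and 85%. False calls were 10.1%, 7.02%, 6.79% and 8.33% of calls. Each pairwise test was also run on all 10 splits of the 6 sums into 3 and 3, and the TNF axis on 24 orders of class names within libraries.

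Alternatives were fixed before the data were examined, and more were added afterwards. They change the scaling, the filter, the tool (DESeq2), the library block, the libraries (each left out in turn), the cells (doublets or cells over 10% mitochondrial or under 500 genes removed) and the weighting of cells. The last takes equal numbers of cells, 28 per class and 21 per macrophage cluster, weights each cell equally and uses limma on log2(CPM + 1). The planned comparison of macrophages with monocytes was not run, as no class of the authors is named monocytes. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.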

Results

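Leukocytes of the sciatic nerve were counted cell by cell in 3 libraries of CD45+ cells from NOD.AIRE GW/+ mice aged 15 weeks. These mice carry 1 altered copy of the thymic regulator Aire. Library 1 holds 6033 cells and 22587246 UMIs, library 2 holds 2333 cells and 11398628 UMIs, and library 3 holds 3274 cells and 13791264 UMIs. Aire, on chromosome 10 from 78030022 to 78043610 (mm10), acts in thymic epithelium and was near absent from nerve leukocytes. It gave 5 UMIs in library 1 (0.221 CPM), 0 in library 2, where 0 allows up to 0.263 CPM, and 1 in library 3 (0.0725 CPM). Fibroblasts were almost missing: their collagen gene Col1a1 gave 12 UMIs in 12 cells. All comparisons are between cell types within nerves of this 1 genotype, since wild-type nerves were not analysed here. The labels do not say whether libraries are separate animals or pools, so p-values measure only the spread between these libraries.

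T cells were the largest part of the nerve leukocytes, at 64.6 ± 7.33% of cells (mean ± SD, n = 3 libraries) over the classes Cd4, Cd8 and Treg. CD4 T cells, which direct other leukocytes through cytokines, made 33.5 ± 3.88%, or 27.1% without deposited cluster 5. That part of the class is of low depth and holds Cd8 as well as Cd4 transcripts. Cytotoxic CD8 T cells made 19.3 ± 1.97%. Tregs, which restrain the other T cells, made 11.8 ± 2.26%, and the class gdT/NK/NKT made 10.6 ± 5.24%. Macrophages, the phagocytes of the nerve, were 4.64 ± 1.39% of cells, and conventional dendritic cells 2.03 ± 1.58% (1.12% without library 1). B cells had the largest SD, and the name of library 1 bears a term, "pos", that the labels do not explain. They made 24% of library 1 (95% interval 22.9 to 25.1), 3.81% of library 2 (3.07 to 4.67) and 12.7% of library 3 (11.6 to 13.9). Their mean was 13.5 ± 10.1%, or 8.25% without library 1. The Mixed class made 3.01 ± 1.98% (1.87% without library 2), pDCs 1.12 ± 1.16% (0.501% without library 1) and plasma cells 0.566 ± 0.479% (0.315% without library 3). Macrophages, cDCs and pDCs together made 7.79 ± 3.91%.

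**Figure D1:**
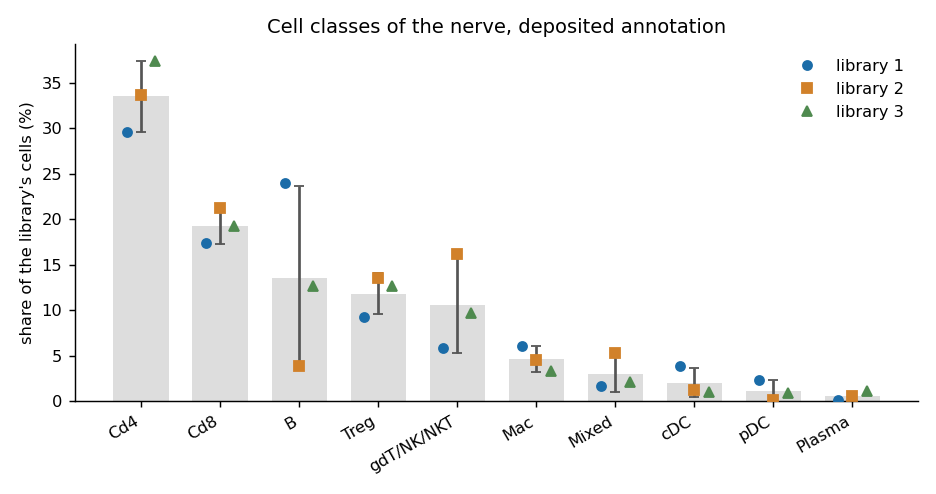
Percent of cells in each of the authors' 10 classes. Bars are means over 3 libraries, lines are SD, and points are single libraries.

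Tnf, the cytokine of the study's title, was highest in macrophages among the 8 tested classes, at 150.2 ± 93.5 CPM (n = 3). The Mixed class came next at 83.7 ± 26.9 CPM. In library 1 this order was turned, with 48.98 CPM in macrophages and 109.7 CPM in the Mixed class after TMM scaling. Against the mean of the other classes macrophages stood higher by a log2 fold change of 2.75 ± 0.25 (SE, adjusted p = 8.51e-10, edgeR quasi-likelihood), or 3.38 without library 1. For the Mixed class this was 1.89 ± 0.37 (adjusted p = 0.000601, edgeR). With equal cells in limma neither call held: Tnf was 2.06 in macrophages (adjusted p = 0.0638) and 2.29 in the Mixed class (adjusted p = 0.0872). CD4 T cells held 36.3 ± 11.8 CPM of Tnf (0.57, not called, adjusted p = 0.082, edgeR) and CD8 T cells 21.3 ± 5.87 CPM. The mean of cDCs, 26.4 ± 23.4 CPM, rests on library 3 (15.0, 10.9 and 53.3 CPM in libraries 1, 2 and 3, with 25, 3 and 14 UMIs). Neither cDCs nor CD8 T cells were called. Tnf was lower in B cells (5.97 ± 3.30 CPM, log2 fold change −2.04, or −2.64 without library 1). It was also lower in Tregs (12.4 ± 2.43 CPM, −1.21) and gdT/NK/NKT (11 CPM, −1.38), but without library 3 these calls ended, at −1.14 and −1.18. Macrophages are few, so CD4 T cells held a similar part of all Tnf UMIs: 29.8 ± 4.98% against 27.2 ± 9.87% in macrophages and 15.2 ± 3.69% in CD8 T cells. Tnf lies on chromosome 17 at 35199381 to 35202007, between Ltb (35194439 to 35196320) and Lta (35203165 to 35205351).

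The gene for TNF release and that for 1 of the 2 TNF receptors were also highest in macrophages. Adam17, the protease that sheds TNF from the membrane, was 159 ± 19.2 CPM in macrophages (log2 fold change 1.69 ± 0.12, adjusted p = 1.01e-11, edgeR, n = 3). Tnfrsf1a, which codes for the widely acting receptor TNFR1, was 157 ± 45.3 CPM there (2.65 ± 0.19, adjusted p = 6.1e-12, edgeR). Neither was called in macrophages with equal cells in limma (Adam17 1.27, adjusted p = 0.0723, Tnfrsf1a 2.97, adjusted p = 0.0632). In cDCs it was 86.1 ± 29.3 CPM (1.5, or 2.11 without library 1), in CD4 T cells 16.0 ± 7.88 CPM (−1.07) and in B cells 4.27 ± 3.70 CPM (−2.81). Tnfrsf1b, for TNFR2, which helps Tregs expand, was highest in Tregs at 212 ± 90.0 CPM (1.03 ± 0.12, adjusted p = 2.79e-07, edgeR). Macrophages had 170.1 ± 88.6 CPM of Tnfrsf1b (0.59 ± 0.13) and CD4 T cells 156 ± 61.5 CPM (0.56, not called without library 1 at 0.36). Tnfrsf1b was lower in B cells (60.4 ± 30.5 CPM, −1.08) and in cDCs (75.9 ± 45.5 CPM, −0.89, not called without library 1 at −0.41). Adam17 was lower in CD8 T cells (39.6 ± 10.7 CPM, −0.62). It was also called lower in CD4 T cells (−0.46) and Tregs (−0.50). The first of these ended without library 1 (−0.44) or library 2 (−0.35), and the second without library 1 (−0.57) or library 3 (−0.44).

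Transcripts of the lymphotoxins, relatives of TNF that shape lymphoid tissue, were highest in lymphocyte classes and the Mixed class. Those of the lymphotoxin beta receptor were highest in macrophages and cDCs among the 8 tested classes. Lta was 45.7 ± 13.4 CPM in CD4 T cells (log2 fold change 3.17 ± 0.25, adjusted p = 5.08e-10, edgeR, n = 3). Lta was also higher in the Mixed class (25.8 ± 21.7 CPM, 2.25, not called without library 3 at 2.26) and in B cells (20.0 ± 6.23 CPM, 1.5, 2.25 without library 3, not called without library 1 at 1.80). Macrophages held 2 UMIs of Lta against 870 in the other classes, a ratio of 0.0227 (counting interval 0.00275 to 0.0823), and cDCs held 1, a ratio of 0.0193 (0.000488 to 0.108). Both were called lower by edgeR, but in macrophages not without library 1 (fitted log2 fold change −2.26), and in cDCs neither without library 1 (−7.25) nor library 3 (−3.28). Ltb was 911 ± 62.7 CPM in the Mixed class (1.62 ± 0.27) and 679.5 ± 124 CPM in Tregs (1.13). It was 639.8 ± 139 CPM in CD4 T cells (1.03, not called without library 1 at 0.94) and 535 ± 80.2 CPM in B cells (0.74, not called without library 1 at 0.84 or library 2 at 0.52). In macrophages Ltb was 38.4 ± 51.4 CPM (−3.82, or −3.07 without library 1 and −5.52 without library 3), and in cDCs 109 ± 60.1 CPM (−1.75). Ltbr, the lymphotoxin beta receptor gene, was 51.6 ± 15.0 CPM in macrophages and 29.3 ± 8.23 CPM in cDCs (adjusted p = 1.36e-14 and 1.05e-10, edgeR). In the other 6 tested classes its mean was 0.513 CPM or less.

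**Figure D2:**
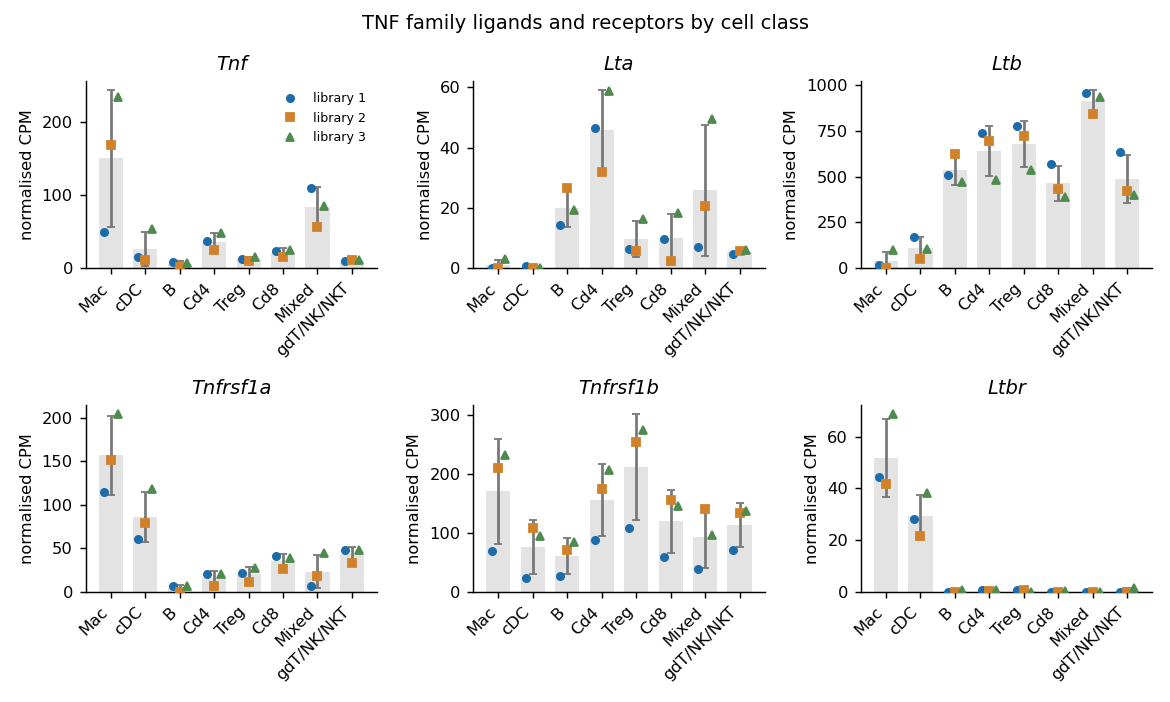
Level of TNF family ligands and receptors by cell class, in normalised CPM. Bars are means over 3 libraries, lines are SD, and points are single libraries.

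Genes that carry the TNF signal inside cells differed between classes as well. Ripk1, the kinase at the fork between survival and death, was 64.2 ± 22.6 CPM in macrophages (log2 fold change 0.79 ± 0.14, adjusted p = 5.52e-05, edgeR, n = 3), and Rela, an NF-kB subunit, 84.1 ± 33.4 CPM (0.61 ± 0.15). Birc3, an NF-kB-induced ubiquitin ligase, was higher in B cells (151 ± 18.7 CPM, 1.15) and macrophages (136 ± 25 CPM, 0.95), while its relative Birc2 was lower in macrophages (38.0 ± 5.96 CPM, −1.35) and higher in gdT/NK/NKT (133.8 ± 74.8 CPM, 0.62). CD8 T cells were lower in Birc3 (31.5 ± 1.31 CPM, −1.43) and Nfkb1 (93.8 ± 54.0 CPM, −0.91), and gdT/NK/NKT were lower in Birc3 (−0.81) and Traf1 (109 ± 20.3 CPM, −0.99). Traf1, an adaptor of TNFR2, was highest in cDCs (518 ± 199 CPM, 1.51 ± 0.18), which were also higher in Ikbkb (167 ± 59.0 CPM, 0.87). Tab2 was higher in gdT/NK/NKT (165 ± 81.5 CPM, 0.95) and lower in B cells (54.2 ± 34.8 CPM, −0.73). Traf2 was called in no class by edgeR, DESeq2 or limma, and at an unadjusted p under 0.05 in 0 of 8. In all, 62 of 144 pairs of gene and class were called (36 higher and 26 lower), and 69 adjusted over the list alone. Without library 1, 2 or 3 the total was 45, 49 or 52, without the library block 30 and with equal cells in limma 15, and 33 of the 62 calls held whichever library was left out. The 14 of the 62 that limma kept with equal cells were Traf1, Ltbr and Ltb in macrophages and in cDCs, Tnf, Tnfrsf1a, Lta, Birc3 and Tab2 in B cells, Birc3 in CD8 T cells, Ikbkb in the Mixed class and Tab2 in gdT/NK/NKT. As a whole the TNF list passed camera only in CD8 T cells, downwards (adjusted p = 0.0207). There 1 of its 18 genes was higher and 4 lower (5 adjusted over the list alone, adjusted p = 0.217 with an estimated correlation). By edgeR macrophages had the most calls, 10 higher and 4 lower, but with equal cells in limma B cells had 5 and macrophages and cDCs 3 each.

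Some calls of these signalling genes ended when a library was left out. For Nfkb1 they were the Mixed class (0.61, ended without library 2 at 0.42), macrophages (0.43, ended without library 2 at 0.51 and library 3 at 0.15) and CD4 T cells (0.38, ended without library 1 at 0.28 and library 2 at 0.38). Traf1 calls ended in Tregs (0.56) without library 1 (0.44) or 2 (0.54), in CD4 T cells (0.48) without library 1 (0.29) and in B cells (−0.65) without library 1 (−0.72). In macrophages Traf1 (−0.75) ended without library 1 (−0.50) or 2 (−0.51). Birc3 calls ended in Tregs (0.36) without library 1, 2 or 3 (0.32, 0.34 and 0.34), in cDCs (0.44) without library 3 (0.29) and in CD4 T cells (−0.32) without library 2 (−0.23) or 3 (−0.33). Birc2 calls ended in CD4 T cells (0.41) without library 1 (0.26) or 3 (0.33), and in cDCs (0.44) without library 2 (0.17). Ikbkb calls ended in Tregs (−0.46) without library 1 (−0.55) or 2 (−0.33) and in the Mixed class (−0.79) without library 1 (−0.73) or 3 (−0.70). Rela in CD8 T cells (−0.42) ended without library 2 (−0.43) or 3 (−0.45). Map3k7 in macrophages (0.48) ended without library 1, 2 or 3 (0.77, 0.54 and 0.35), as did Tradd in CD8 T cells (0.39, then 0.36, 0.39 and 0.40). Without deposited cluster 5, which is part of the CD4 class, higher calls in CD4 T cells ended for Tnfrsf1b (0.33), Traf1 (0.47), Nfkb1 (0.30) and Birc2 (0.28), as did Tradd in CD8 T cells (0.32). With 1 lower call gained, CD4 T cells then had 2 genes higher and 4 lower.

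Single cells with Tnf were frequent among macrophages, which respond to microbial products with this cytokine, and in the Mixed class. With every cell thinned to 1000 UMIs, Tnf was seen in 10.7 ± 5.81% of macrophages (n = 3), 7.77 ± 3.11% of the Mixed class and 3.68 ± 1.31% of CD4 T cells. It was seen in 2.96 ± 0.776% of cDCs, 2.18 ± 0.745% of CD8 T cells, 1.40 ± 0.679% of Tregs and 0.893 ± 0.546% of gdT/NK/NKT. B cells, taken as the background, gave 0.296 ± 0.316% (0.130% without library 1). The order of the first 2 depends on depth and library: thinned to 2000 UMIs, macrophages gave 14.3% and the Mixed class 14.6%. At 1000 UMIs macrophages gave 4.13% and the Mixed class 11.1% in library 1. The Mixed class was lowest in library 2, at 4.96%. Macrophages are deeper than T cells (median 7434 UMIs against 2504.5 in CD4 T cells). In all their UMIs Tnf was seen in 34.7 ± 16.0% of macrophages.

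Macrophages differed from T cells in 5375 of 10613 tested genes (edgeR, n = 3), 2811 higher and 2564 lower. The larger side turned without scrublet doublets (2513 higher, 3068 lower), with no filter on low counts (2831 and 3537) and in a fit of the compared classes alone (2419 and 2527). With the fixed list of cell type markers set aside, the largest rises included genes of innate defence. Lyz2, Izumo1r and Ifng were not on that list but are among the genes that lead clusters of the authors. Their differences below only identify classes. Complement factor Cfb was 271 ± 336 CPM in macrophages against 0.138 in T cells (log2 fold change 10.58 ± 0.38, adjusted p = 6.01e-13). The inflammasome sensor Nlrp3 was 275 ± 117 against 0.129 CPM (10.43 ± 0.37, adjusted p = 1.72e-14), and the monocyte attractant Ccl2 454 ± 271 against 0.311 CPM (10.15 ± 0.36). Pla2g7, which cleaves platelet-activating factor, was 544 ± 261 against 0.301 CPM (10.48, or 9.88 without library 2), and the matrix gene Thbs1 333 ± 243 against 0.149 CPM (10.39, 12.64 without library 1, 9.38 without library 2). The C5a receptor gene C5ar1 was 285 ± 174 against 0.158 CPM (10.23, or 11.11 without library 1), the lysozyme gene Lyz2 11521 ± 5495 against 12.7 CPM (10.18, 11.44 without library 1, 8.92 without library 2), and Mgst1 252 ± 46.3 against 0.168 CPM (10.10). T cells in turn led in Ifng, the cytokine that activates macrophages, at 207 ± 51.5 against 9.12 ± 10.7 CPM (−4.84 ± 0.47, −4.04 without library 1, −6.12 without library 3). They also led in Ctla2a (−5.00 ± 0.48, adjusted p = 2.21e-08), Nrgn (−4.97), S1pr4 (−4.94) and Gimap9 (−4.70). The same held for Sytl3 (−4.94, −6.10 without library 3), Izumo1r (−4.78, −5.97 without library 3) and Klk8 (−4.78, −3.94 without library 1, −5.56 without library 3). Without library 1, 2 or 3 the genes called were 3397, 4615 or 4894, without the library block 2872 and with equal cells in limma 1498.

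Programmes that held with a correlation estimated per list were of inflammatory and scavenging macrophages. Some of these lists hold genes that lead the authors' macrophage cluster, such as C1qa, Apoe and Lyz2. Cells were classed by the same counts, so the rise of such genes only identifies the class. Of the lipid-handling list 14 of 14 genes were higher (14 adjusted over the list alone, camera with an estimated correlation adjusted p = 0.035). Among them were Arg1 (8.84, 9.85 without library 1), Plin2 (5.28), Lgmn (8.07, 7.22 without library 2) and the lipid receptor gene Trem2 (744 ± 620.0 CPM, 9.42, 11.90 without library 1, 8.33 without library 2). Complement had 9 of 9 higher (9 alone, adjusted p = 0.00656), with C3 (8.65, 9.47 without library 1) and C3ar1 (8.37, 10.63 without library 1). The interferon-gamma response had 16 of 18 higher (16 alone, adjusted p = 0.035): the T cell attractant Cxcl9 (1601 ± 1020 CPM, 9.40, 10.39 without library 1), Irf8 (3.95), Ciita (6.08) and Gbp2 (3.32). Monocyte-attracting chemokines had 6 higher and 1 lower of 8 (7 alone, adjusted p = 0.035), with Ccl12 (9.94), Ccl7 (8.70, 7.98 without library 2) and Ccl9 (5.47). The monocyte-derived list had 10 of 12 higher (10 alone, adjusted p = 0.035): Ly6c2 (9.90, 9.25 without library 3), Chil3 (11.39, 13.73 without library 1, 10.59 without library 2, 10.71 without library 3), Plac8 (6.46, 5.86 without library 3) and Fn1 (9.51, 11.02 without library 1). The endoneurial list, of macrophages between the nerve fibres, had 8 higher and 1 lower of 10 (9 alone, adjusted p = 0.0362). Among them were Cst3 (5792 ± 2476 CPM, 4.48), Olfml3 (6.51) and Tmem119, with 3 UMIs in T cells, a ratio of 481 (counting interval 163 to 2348). The epineurial list, of macrophages of the nerve sheath, had 4 of 4 higher (4 alone, adjusted p = 0.035): F13a1 (8.91), Timd4 (5.75), Clec10a (3.30) and Mgl2. Mgl2 had 2 UMIs in T cells, a ratio of 72.7 (counting interval 18.1 to 635), and was not called without library 1 (fitted log2 fold change 3.93). The other genes of this list were not tested. Among them Lyve1 was 0, 1.56 and 6.96 CPM in M1, M2 and M3 and Folr2 1.19, 6.24 and 2.98 CPM, unscaled. F13a1 also leads M3, and Timd4 is among the genes that lead the authors' cDC cluster, so the 4 tested genes do not single out sheath macrophages.

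Other lists passed camera at its set correlation but not with an estimated one. NF-kB targets, switched on by TNF, had 17 higher and 1 lower of 22 (18 adjusted over the list alone, camera adjusted p = 7.39e-06, but adjusted p = 0.0595 with an estimated correlation), with Tnfaip2 (8.91), Sod2 (2.52) and Ptgs2 (8.53, 11.09 without library 1). For Cxcl1 T cells held 1 UMI, a ratio of 1164 (counting interval 206 to 46205). Type I interferon genes had 13 of 14 higher (13 alone, adjusted p = 0.0595 with an estimated correlation), with Oasl2 (5.38), Rsad2 (4.05), Irf7 (2.26) and Bst2 (2.50). MHC class II had 10 of 10 higher (10 alone, adjusted p = 0.0595 with an estimated correlation), with Cd40 (6.98), H2-DMa (4.58) and H2-DMb1 (8.96, 8.17 without library 2). Glycolysis had 10 higher and 2 lower of 14 (12 alone, adjusted p = 0.119 with an estimated correlation), with Hk2 (4.45), Tpi1 (1.88), Pgam1 (1.43) and Pfkl (1.42). The dissociation response had 12 of 15 higher (13 alone, adjusted p = 0.144 with an estimated correlation), with Atf3 (1177 ± 185 CPM, 6.88), Zfp36 (3.79), Fos (3.46) and Jun (3.37).

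T cell lists were lower in macrophages as wholes by camera at its set correlation, but not with an estimated one. Some of their genes, such as Foxp3 and Gzmk, lead T cell clusters of the authors, so their fall only identifies the classes. Th1 genes fell in 11 of 12 (11 adjusted over the list alone, adjusted p = 0.0691 with an estimated correlation), with Cxcr3 (−2.99) and Xcl1 (−4.67, −5.68 without library 1). For the helper cytokine Il21 macrophages held 2 UMIs, a ratio of 0.00884 (counting interval 0.00107 to 0.032). Cytotoxic genes fell in 11 of 11 (11 alone, adjusted p = 0.0603 with an estimated correlation): Prf1, for perforin (−4.44), Gzmk (−3.93, −6.16 without library 3), Klrd1 (−4.26, −5.54 without library 3) and Ctsw (−3.83, −5.14 without library 3). Inhibitory receptors had 3 higher and 6 lower of 9 (9 alone, adjusted p = 0.119 with an estimated correlation), with Lag3 (−3.39), Tox (−4.33, −5.36 without library 3) and Tigit (−2.79, −4.28 without library 3). For Cd160 macrophages held 2 UMIs, a ratio of 0.0231 (counting interval 0.00279 to 0.084). The regulatory T cell list fell in 10 of 10 genes (10 alone, adjusted p = 0.121 with an estimated correlation): Foxp3 (−3.54, −4.45 without library 3), Tnfrsf18 (−3.93, −5.37 without library 3), Gata3 (−3.53, −2.59 without library 1, −5.13 without library 3) and Il10 (−3.44, −4.32 without library 3). Residency genes fell in 6 of 7 (6 alone, adjusted p = 0.121 with an estimated correlation): Rgs1 (−1.19), Cxcr6 (−4.33, −5.32 without library 3), Itgae (−3.38, −4.08 without library 1) and Bhlhe40 (−1.38, not called without library 1 at −1.31). Naive genes had 1 higher and 5 lower of 7 (6 alone, adjusted p = 0.192 with an estimated correlation): S1pr1 (−4.08), Il7r (−3.44), Tcf7 (−4.02, −2.96 without library 1, −6.29 without library 3) and Lef1 (−4.50, −3.57 without library 1, −6.89 without library 3). Proliferation fell in 10 of 11 (10 alone, adjusted p = 0.119 with an estimated correlation), with Mcm5 (−2.72), Top2a (−2.96, −2.30 without library 1) and Tyms (−2.51, −3.28 without library 1). For Ube2c macrophages held 2 UMIs, a ratio of 0.0246 (counting interval 0.00297 to 0.0893). Lists that did not pass camera were the TNF axis (8 higher and 4 lower of 18, 12 alone, adjusted p = 0.188), T cell-attracting chemokines (4 higher and 2 lower of 10, 7 alone, adjusted p = 0.0653) and Th17 (adjusted p = 0.228). Of 6 Th17 genes edgeR, DESeq2 and limma called 0, and 2 had an unadjusted p under 0.05. The same held for myelin (1 higher and 2 lower of 4, 4 alone, adjusted p = 0.307) and hedgehog genes (2 higher and 1 lower of 3, 3 alone, adjusted p = 0.51).

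Of the genes that met the naming rule, Tnfsf8 and Tnfsf11 stood furthest above CD8 T cells in CD4 T cells. Both also lead the largest CD4 cluster of the authors, so their levels only identify it. Tnfsf8, for CD30 ligand, was 707 ± 329.8 CPM in CD4 against 30.8 ± 25.7 CPM in CD8 T cells (log2 fold change 4.54 ± 0.41, adjusted p = 4e-08, edgeR, n = 3). Tnfsf11, for RANKL, which drives osteoclast and dendritic cell survival, was 184.5 ± 57.5 against 14.5 ± 5.28 CPM (3.72 ± 0.34). Also higher in CD4 T cells were Tiam1 (143 ± 38.3 against 16.4 ± 7.25 CPM, 3.12), the cytokine receptor Il6ra (63.7 ± 11.6 against 7.75 ± 1.16 CPM, 3.01), the chemokine receptor Ccr8 (3.24) and Tmem176b (3.23). Ifitm2 (3.44, 4.12 without library 1) and Spp1, for osteopontin (189.5 ± 56.0 against 24.3 ± 22.8 CPM, 3.08, 3.95 without library 1), followed. CD8 T cells led in the natural killer receptors Klrc1 (321 ± 285 against 46.3 ± 72.1 CPM, −3.58, −2.93 without library 2, −4.97 without library 3), Klrk1 (246 ± 32.7 against 29.9 ± 28.6 CPM, −3.20, −4.09 without library 3) and Klrd1 (−3.18, −2.57 without library 2, −3.92 without library 3). They also led in Gzmb, for granzyme B (312 ± 132 against 53.4 ± 59.2 CPM, −2.91, −3.90 without library 3), Cd7 (−3.12, −3.89 without library 3), Lrrk1 (−2.75, −4.24 without library 3), Ier3 (−2.66) and Hopx (−2.54). In all 1554 of 10895 genes were called, 834 higher in CD4 and 720 higher in CD8 T cells. Without library 1, 2 or 3 this was 662, 1002 or 1109, without the library block 150.0 and with equal cells in limma 58.

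**Figure D3:**
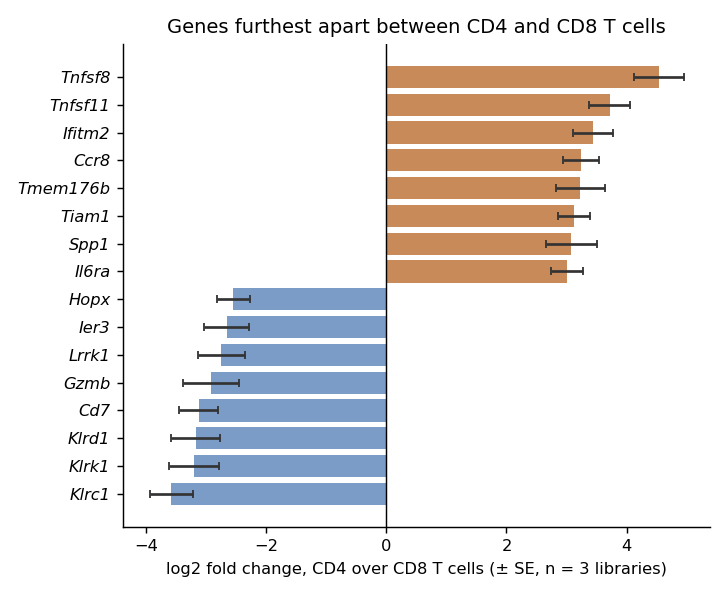
Log2 fold change between CD4 and CD8 T cells of the genes with the largest rises and falls. Lines are the standard error from the fit over 3 libraries.

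Cytotoxic and proliferation genes were the 2 lists that held with a correlation estimated per list. Of the cytotoxic list, Gzmk and Ccl5 are among the genes that lead the authors' CD8 cluster 3, so their levels only identify the class. Of 11 cytotoxic genes 11 were lower in CD4 T cells (11 adjusted over the list alone, camera adjusted p = 4.69e-13, adjusted p = 0.0151 with an estimated correlation), with Gzmk (−2.79) and Gzma (111 ± 13.4 CPM in CD8 T cells, −3.42). Of 12 proliferation genes 12 were lower (12 alone, adjusted p = 0.0165 with an estimated correlation): Ube2c (−3.36), Birc5 (−4.05, −3.25 without library 1, −4.67 without library 3), and the cyclins Ccnb1 (−2.95) and Ccnb2 (−4.71, −4 without library 1, −6.00 without library 3). Division was not a trait of all CD8 T cells: Birc5 was 1.81 CPM in the authors' CD8 cluster 3 and 2.00 CPM in CD4 cluster 0, against 79.1 CPM in CD8 cluster 4, which is led by proliferation genes. Top2a was 22.9, 27.5 and 201 CPM in these clusters. The TNF list had 5 higher and 1 lower of 18 (9 alone, camera adjusted p = 0.00527, but adjusted p = 0.232 with an estimated correlation): Lta (2.19 ± 0.29), Nfkb1 (1.13) and Birc3 (0.98) were higher in CD4 T cells and Tnfrsf1a (−1.15) lower. The regulatory list had 8 of 10 higher (10 alone, adjusted p = 0.232 with an estimated correlation), with Tnfrsf4, for OX40 (1066 ± 97.0 against 138 ± 62.4 CPM, 2.94), Il10 (2.53, 3.26 without library 1), Il2ra (1.94) and Gata3 (1.36). T cell-attracting chemokines had 1 higher and 4 lower of 10 (6 alone, adjusted p = 0.232 with an estimated correlation), with Ccl5 (22266 ± 7681 CPM in CD8 against 1231 ± 363 CPM in CD4 T cells, −4.23), Xcl1 (−2.37), Ccl3 (−1.77) and Ccl4 (−1.99, not called without library 1 at −2.07). Of 14 type I interferon genes 2 were lower (6 alone, adjusted p = 0.387 with an estimated correlation): Ifit3 (−2.14, −3.07 without library 3) and Ifit1 (−1.21, not called without library 3 at −1.27), while Rsad2 and Rtp4 were not called. Of 9 inhibitory receptors 2 were lower (2 alone, adjusted p = 0.232 with an estimated correlation): Cd160 (−2.76) and Havcr2 (−1.52, −2.57 without library 3, not called without library 1 at −1.23 or library 2 at −0.94). Entpd1 and Ctla4 were not called. The dissociation list had 4 of 15 higher (5 alone, adjusted p = 0.432 with an estimated correlation): Junb (0.73), Dusp1 (1.14), Atf3 (2.51, 3.16 without library 1) and Fosb (0.88, not called without library 1, 2 or 3 at 0.87, 0.94 and 0.87, nor without deposited cluster 5 at 0.88).

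Macrophages of the nerve fell into 5 clusters. M1 (215 cells) was led by Apoc2, Arg1 and Acod1, M2 (163 cells) by Gdf15, Cxcl13 and Vcam1, and M3 (142 cells) by the monocyte genes Ccr2 and Chil3. M5 (25 cells) was led by S100a9, S100a8, Ace and Adgre4. S100a9 was seen in only 4 cells of the whole dataset. The monocyte gene Ace was 696 CPM and C1qa 9.28 CPM in M5, unscaled. M4 (36 cells) held T cell genes at a median of 2006 UMIs and was given no name. Tnf was 135.8 ± 100.4 CPM in M1, 85.7 ± 41.6 CPM in M2 and 117.5 ± 94.5 CPM in M3 (n = 3), and it was not called between M1 and M3. Of 15 tested TNF axis genes edgeR, DESeq2 and limma called 0 between M1 and M3 (0 adjusted over the list alone), although without library 3 edgeR called 1, lower in M1. With all libraries 3 had an unadjusted p under 0.05 (camera adjusted p = 0.277). M2, with 8 cells in library 3, fell short of the 20 cells asked for. Of M1, M2 and M3 it held the most Ccl8 (5713 ± 1999 CPM), a chemokine of resident macrophages, and the most C1qa (9618 ± 5933 CPM).

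Genes of antigen presentation were higher in M1, and 4 of 12 monocyte-derived genes were higher in M3. Ly6c2, a classical monocyte gene, was not called between them, at 449.8 CPM in M1 and 640.3 CPM in M3 of library 1, 444 and 436 CPM in library 2 and 1209.8 and 1098 CPM in library 3, unscaled. The MHC class II gene H2-Aa was 11190 ± 8821 CPM in M1 against 2269 ± 1657 CPM in M3 (log2 fold change 2.21 ± 0.14, adjusted p = 2.8e-05, edgeR, n = 3). Cd74 (1.88), H2-Eb1 (2.33) and H2-Ab1 (1.98) went with it, 6 of 9 of the list in all (7 adjusted over the list alone, camera adjusted p = 5.96e-07, but adjusted p = 0.338 with an estimated correlation). C1qa, the complement subunit that tags debris, was 2707 ± 2370.5 against 225 ± 197 CPM (3.56 ± 0.20), though in library 3 M1 held 12 CPM of it. C1qc (3.76) and C1qb (3.28) rose with it. Complement had 4 higher and 1 lower of 9 (5 alone, adjusted p = 0.362 with an estimated correlation). Lipid handling had 9 of 14 higher (10 alone, adjusted p = 0.338 with an estimated correlation), with Apoe (24744 ± 28892 against 3428 ± 3829.6 CPM, 2.50), Fabp5 (2.97, 3.77 without library 2) and Cd9 (2.93). T cell-attracting chemokines had 5 of 7 higher (5 alone, adjusted p = 0.338 with an estimated correlation): Ccl8 (228 ± 208 against 3.83 ± 3.46 CPM, 5.87 ± 0.60), Ccl5 (3987 ± 1307 against 931 ± 569 CPM, 2.26), Cxcl16 (1.28) and Cxcl9 (1.11, not called without library 2 at 0.86). NF-kB targets had 4 of 22 higher (5 alone, adjusted p = 0.463 with an estimated correlation): Bcl2a1b (1.76), Il1b (3883 ± 1765 against 1988 ± 915 CPM, 0.96), Ccl4 (1.34) and Tnfaip3 (0.84, not called without library 1 at 0.74 or library 2 at 0.88). The endoneurial list had 4 of 6 higher (4 alone, adjusted p = 0.362 with an estimated correlation), with Tmem119 (3.67) and Trem2 (1.31, not called without library 2 at 1.17). For Olfml3 M3 held 1 UMI, a ratio of 41.8 (counting interval 7.26 to 1673). Ms4a7 (3.67), Zmynd15 (3.19), Ccl12 (392 ± 179 against 48.0 ± 20.3 CPM, 3.13), Gpnmb (3.09) and Apoc4 (3.06, not called without library 2 at 2.18) were also higher. Without library 1 Ms4a7, Apoc4 and Cd9 were too low to be tested, and Ccl8, Zmynd15, Gpnmb, Tmem119 and Olfml3 without library 1 or library 2.

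M3 led in Ifitm6 (194 ± 141 against 24.2 ± 33.5 CPM, log2 fold change −3.12 ± 0.38, adjusted p = 0.00151, edgeR, n = 3, −3.87 without library 3). It also led in the chemokine Ccl6 (−2.18, −2.84 without library 3), in Fam49a (−2.11, not called without library 1 at −2.29 or library 2 at −1.93) and in Ltb4r1 (−2.03, not called without library 2 at −1.83). F13a1 (−2.26, −3.18 without library 3) was −1.57 without library 1 and not called without library 2 (−2.16). Cd177 (−2.08, −3.64 without library 3) was not called without library 1 (−1.22) or 2 (−2.08), Ear2 (−2.05, −3.08 without library 3) not without library 1 (−1.80), and Alcam (−1.90) not without library 1 (−1.55) or 2 (−1.85). The monocyte-derived list fell in 4 of 12 (9 adjusted over the list alone, adjusted p = 0.362 with an estimated correlation): Fn1 (−1.24), S100a6 (−1.54, not called without library 2 at −1.31), S100a4 (−1.76, −2.49 without library 3) and Plac8 (−1.34, −1.97 without library 3). S100a4 was not called without library 1 (−1.37) or 2 (−1.39), nor Plac8 (−1.13 and −0.93). The dissociation list had 5 of 15 higher in M1 (11 alone, adjusted p = 0.362 with an estimated correlation): Atf3 (0.80, not called without library 1 at 0.80 or 2 at 0.91), Egr1 (2.03, 2.63 without library 2, not called without library 1 at 1.42), Junb (0.59, not called without library 1 at 0.62 or 2 at 0.59) and Fos (0.70, not called without library 1 at 0.52). Type I interferon genes passed camera (adjusted p = 0.00341, but adjusted p = 0.362 with an estimated correlation) but edgeR, DESeq2 and limma called 0 of 11. At an unadjusted p under 0.05, and adjusted over the list alone, there were 4: Isg15, Bst2, Irf7 and Ifit2. Isg15 is among the 10 genes that lead M1. Of 3 cytotoxic genes Ccl5, higher in M1, was the 1 called (2 over the list alone, adjusted p = 0.362 with an estimated correlation), not Nkg7 or Klrk1. In all 201 of 4891 genes were called, 131 higher and 70 lower in M1. Without library 1, 2 or 3 they were 59, 70 or 473, and with equal cells in limma 5. Without the library block edgeR called 0 (229 of 4199 at an unadjusted p under 0.05), and DESeq2 with the block called 105.

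**Figure D4:**
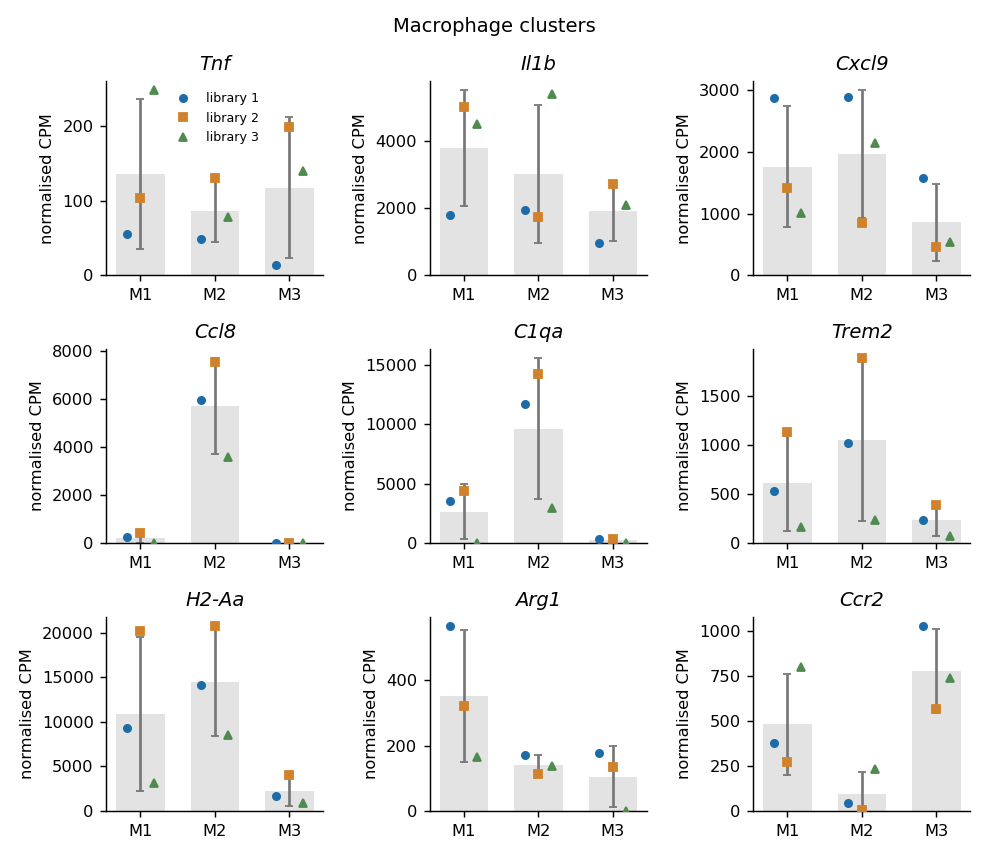
Level of Tnf and of 8 other genes in macrophage clusters M1, M2 and M3, in normalised CPM. Bars are means over 3 libraries, lines are SD, and points are single libraries.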

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

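The 2 predictions on pDCs were written before their tests, and no test of this part was chosen after its result was seen. Plasmacytoid dendritic cells are known as makers of type I interferon, and no comparison uses them, as library 2 holds 2. They drew attention because a signal stood in cells outside the tests: in library 3, 30 pDCs held 108 Tnf UMIs, 474 CPM (counting interval 389 to 572), above the 13.2 CPM that a count of 0 allows. In library 1, 143 pDCs held 4 Tnf UMIs, 4.51 CPM (1.23 to 11.5), where the pDC genes Siglech and Ccr9 were 2748 and 1773 CPM against 2445 and 1488 CPM in library 3, Tcf4 1631 against 698 CPM and Bst2 4029 against 5934 CPM. A single cell as the source is ruled out: Tnf was seen in 10 of the 30 cells, and the cell with the most held 38.9% of the UMIs. Macrophage RNA or doublets with macrophages are ruled out too, since 5 macrophage markers had a median ratio of 0 to their level in macrophages of library 3 (highest 0.00059), while the Tnf ratio was 2.13. The signal stands in 1 library, and no biological explanation was tested. Library 3 is also the only 5′ library, and library 2, a 3′ library, holds too few pDCs to compare. An effect of the chemistry on Tnf, and on the interferon genes below, was not tested and stays open. In each of the tested classes unscaled Tnf was higher in library 3 than in library 2, by 1.16 (gdT/NK/NKT) to 5.65 times (cDCs). In the same cells of library 3 the interferon genes Irf7 and Isg15 were 636 and 176 CPM, against 121 and 6.76 CPM in library 1.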

How the results depend on the processing

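Alternatives chosen only after the results were seen leave out deposited cluster 5, the 5% of cells with the highest doublet scores, macrophages outside M1 to M3, or Gm42418, AY036118, Malat1 and mitochondrial genes, redraw the macrophage clusters, or leave libraries out of the list tests. Of the TNF axis values 1839 of 2016 kept their side of the threshold. Of those for macrophages against T cells 1267 of 1289 did, for CD4 against CD8 558 of 643 and for M1 against M3 555 of 678. These totals include results never called: 82 of the 144 TNF axis pairs were not called, and count as kept while they stay so. Of the 62 called, 33 held whichever library was left out. Direction was compared only for values called in the main fit, so values not called could change sign and still count as kept. Tnf in cDCs, which was not called, ranged from −0.70 to 1.41. Values called in the main fit reversed only with equal cells in limma, where Adam17 in CD8 T cells was 0.0291, Birc3 in CD4 T cells 0.55 and Nfkb1 in macrophages −0.0851. The cause was not tested.

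Without the library block, which pairs classes of the same library, calls fell from 62 to 30 for the TNF axis, from 5375 to 2872 for macrophages against T cells, from 1554 to 150.0 for CD4 against CD8 and from 201 to 0 for M1 against M3. For that last 0, edgeR without the block gave 229 of 4199 genes at an unadjusted p under 0.05, and DESeq2 with the block called 105. Of the named results called in the main fit, 32 of 62, 5 of 86, 27 of 42 and 38 of 44 lost their call without the pairing. For M1 against M3, 6 of the 50 named genes were not tested without it. With equal cells in limma, which keeps fewer cells, the 4 counts were 15, 1498, 58 and 5. With a fold change over 2 required as well, 797 genes were called between CD4 and CD8 T cells. With no filter on low counts 319 were called between M1 and M3. Leaving out 1 library gave 3397 to 4894, 662 to 1109 and 59 to 473 calls in the 3 pairwise tests, and the cause was not tested. Elsewhere counts stayed within 1.5 times. Without doublets called by scrublet the median log2 fold change of all genes between macrophages and T cells moved from −0.05 to −0.17.

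Lists passing fell from 19 to 7 (macrophages against T cells), 8 to 2 (CD4 against CD8), 10 to 0 (M1 against M3, where camera at its set correlation and fry passed 10 and 4) and 115 to 33 (classes) with an estimated correlation. Fry passed 22 lists for macrophages against T cells, 4 in CD4 against CD8 and 141 for classes. The CD4 share fell from 33.5% to 27.1% without deposited cluster 5, by construction. Cells with Tnf rise with depth. Thinned to 2000 UMIs, and not thinned, they were 1.08% and 2.13% of B cells, 6.42% and 8.74% of CD4, 3.92% and 7.91% of CD8 T cells, 14.6% and 19.7% of the Mixed class, 2.86% and 4.46% of Tregs, 7.01% and 12.1% of cDCs and 1.59% and 4.77% of gdT/NK/NKT. Of macrophages they were 14.3% and 34.7%. At resolution 0.3 M1 and M3 are 1 cluster with no contrast. The alternatives for macrophages against monocytes were not run. Depth limits genes under about 3 UMIs in a class.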

Other observations

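Chosen only after results were seen were the genes of the next 2 paragraphs, for cluster 5 the tests of doublets and of free RNA as the source of both Cd4 and Cd8, and for Tnf in macrophages those of cluster makeup and 5′ chemistry.

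The Mixed class, which no pairwise comparison covers, held interleukin 17 transcripts. Il17a, which draws neutrophils, was 1535 ± 1242 CPM there (n = 3) and at most 1.80 CPM in any other tested class. Il17f (163.8 ± 165.8 CPM), Il23r (72.7 ± 44.8 CPM) and Il1r1 (63.0 ± 15.2 CPM) went with it. Il17a and Il17f are among the 10 genes that lead this cluster, so these levels only identify it. Csf2, for GM-CSF, which acts on macrophages, was 124 ± 57.4 CPM in the Mixed class (8.57 ± 0.86, adjusted p = 5.09e-07, edgeR).

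Other classes held products linked to their known functions, not all of them particular to the class. The class gdT/NK/NKT held the killing genes Gzma at 655 ± 485 CPM and Prf1 at 388 ± 50.3 CPM (n = 3). Tregs held Areg, a growth factor of tissue repair, at 421 ± 146 CPM, and Il10 at 252 ± 73.8 CPM. Conventional dendritic cells held Il1b at 1823 ± 527 CPM and Ccl22, which attracts T cells bearing CCR4, at 105.5, 159 and 22.8 CPM in libraries 1, 2 and 3. Gzma and Areg are among the 10 genes that lead clusters of these classes, and cells were classed by the same counts, so the levels of Gzma and Areg only identify the classes. Il10 is instead among the genes that lead CD4 cluster 6. Il1b was also high in macrophages, at 2834 CPM in M1 (unscaled).

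Deposited cluster 5, named Cd4 by the authors, holds 973 cells, 25.7% of the class (19.1%, 8.55% and 46.2% in libraries 1, 2 and 3), and Cd4 was seen in 23.8%, 26.9% and 35.6% of them by library and Cd8a or Cd8b1 in 15%, 11.9% and 43.5%, so the Cd8 side is mostly of library 3. Doublets of CD4 and CD8 T cells are ruled out as the bulk of the cluster, as its median was 861 UMIs against 3128 and 3660 in clusters 0 and 3. The low depth was known before this test, and a median cannot tell whether a minority of the cells are doublets. Its median mitochondrial percent was 7.05, against 3.23 in cluster 0. Low-depth cells of several T cell lineages grouped together fit: cells with both Cd4 and Cd8 were 36 against 102 expected, a ratio of 0.354 (0.248 to 0.490) that rests on library 3 (29 against 87.5, with 6 against 12.1 and 1 against 2.15 in libraries 1 and 2), where it also rules out free RNA as the source of both. Free RNA of other types is likely an added part, since 13 genes of macrophages, B cells and dendritic cells stood at a median of 2.34 times cluster 0 (1.17 to 3.28), and no biological explanation was tested.

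Tnf in macrophages was lower in library 1, at 37.6 CPM, than in libraries 2 and 3, at a mean of 172 CPM. Different shares of the macrophage clusters are ruled out as the cause, as with the cluster shares of libraries 2 and 3 the level of library 1 would be 37.9 CPM. Genes were scaled within libraries before clustering, so cells under the same cluster name can differ between libraries. M1 held C1qa at 3289, 3585 and 12.3 CPM (unscaled) in libraries 1, 2 and 3. A different makeup of cells within the clusters therefore stays open. The 5′ chemistry of library 3 is ruled out as the whole cause, since library 2, a 3′ library like library 1, lay 3.23 times above it (2.44 to 4.29). A weaker dissociation response in library 1 fits and stays open: that list had a median log2 ratio of −0.54 (quartiles −0.88 to −0.20, 3 of 15 genes higher) between library 1 and the mean of the others. NF-kB targets (−0.83), type I interferon genes (−1.23) and monocyte-derived genes (−0.77) were lower as well, so the ratio does not single out dissociation, and no biological explanation was tested. Among T cell lists, inhibitory receptors (−1.90), cytotoxic genes (−1.80) and the regulatory T cell programme (−1.38) were also lower. Cluster M4, which holds T cell genes, made 3.81% of macrophages in library 1 against 9.43% and 11.1% in libraries 2 and 3. The fall of the T cell lists cannot be told apart from this smaller share.

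With class names reordered within libraries, the TNF axis gave at most 6 calls in 23 other orders against 62, so that 1 of 24 orders, the real one, gave as many. Classes were drawn from the same counts, so this shows only that class names match across libraries. The 10 splits of each pairwise test are too few for a share under 0.05. Macrophages against T cells gave 5375 calls against at most 1 in another split, CD4 against CD8 1554 against at most 3, and M1 against M3 201 against at most 3.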
